A study of Arabidopsis thaliana with 6 samples.

How the data were processed

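Total RNA was extracted from about 80 mg of light-grown seedlings per sample, 5 days old, and about 6 µg was labelled and hybridised to Affymetrix ATH1 arrays, per the labels' protocols. There were 3 wild type and 3 *fbp7-3* mutant samples, both in the Nossen accession, and the group of each came from its title. The deposited values are MAS5 signal intensities, per the submitters' processing notes; the MAS5 version and its settings are not given in the sources used here. They ran from 0.1 to about 46363.1 on a linear scale, with no value below 0. After the lowest and highest 2% were left out, the mean was 500 on each of the 6 arrays, so each array had been scaled by 1 factor, and no detection calls were used here. Such scaling assumes that the overall level is alike on all arrays, and MAS5 signals near background are noisy on a log scale. Array medians lay between 188.7 and 200.7.

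Gene names came from the platform's annotation, as paired with the probe sets in the table used here. Of 22810 probe sets, 64 were controls and were left out of the tests. Of the other 22746, 13513 had 1 named gene (13350 different genes), 503 had several and 8730 were not listed in the table, which leaves them unnamed here. Symbols and gene order came from the RefSeq annotation of assembly TAIR10.1, in which 13436 of the 13513 were found. No coordinates are given because the sources name no build for the array. The annotation table did not pair a probe set with *FBP7*, so the planned test of its level was not run.

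From the deposited intensities, log2(signal + 16) was computed, with no further normalization. Probe sets whose mean log2 value over all 6 arrays lay in the lowest 25% were left out, leaving 17059. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with group as the single term and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Folds and log2 changes are on the log2(signal + 16) scale, which understates changes at low signal; means and SDs of signal are on the linear scale. Gene lists were compared with camera in limma (preset correlation 0.01), with 1 probe set per gene, the brightest, and with adjustment over the lists of at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Single values were compared with two-sided exact permutation tests, for which 3 against 3 cannot give less than 0.1. Figures were drawn with matplotlib 3.10.9.

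The tests, the 25 gene lists (23 by locus and the plastid-encoded and mitochondrion-encoded genes), the rule for naming genes and the alternatives first listed were fixed before the data were examined. The rule took *FBP7* first. It then took, among probe sets with 1 gene, past the threshold and with non-overlapping groups, the 10 with the largest rise and the 10 with the largest fall. From each list it took the 2 members with the smallest p, or up to 4 where more than 4 passed, and it took those of the 5 measured loci on each side of *FBP7* that passed. The lists were written from general knowledge of Arabidopsis, and included heat shock, cold and translation genes, ubiquitin and proteasome genes, photosynthesis, hormone and defence genes, and markers of roots and seeds. Other genes and probe sets in the text were chosen after their values were seen.

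Alternatives were other pseudocounts (1 and 64), other filters, quantile normalization, median centring, other variance models, array weights, the replicate number as a block, each array left out in turn, and other thresholds and list tests. An index of RNA quality as a covariate and adjustment over named probe sets only were added after the data were seen. The index was the mean log2 3′ to 5′ ratio of the actin, GAPDH and ubiquitin control probe sets.

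The comparison was tested on simulated data for the 17059 probe sets, with independent noise of the fitted size and 200 changed probe sets in each of 20 simulations. It recovered 36% of log2 changes of 0.5, 77.8% of 1, 93.7% of 1.5 and 97.8% of 2, and 7% of its calls were false. A simulated list shift of 0.3 in the plastid-encoded genes was called in 100% of the simulations, and 1 of 140 unshifted lists was called. Correlated noise between genes was not simulated. The noise was Gaussian, with variances taken from the fit with the intensity trend, so these rates do not test the choice of that trend.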

Results

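Transcript levels were measured in whole light-grown Arabidopsis seedlings, 5 days old, of the Nossen accession. The wild type was compared with the *fbp7-3* mutant, which carries a mutation in the F-box protein gene *FBP7* (AT1G21760). F-box proteins are the substrate-binding subunits of SCF ubiquitin ligases. Each group held 3 samples, and each sample was hybridised to 1 ATH1 array, so that 6 arrays were compared. Of 22746 probe sets analysed, 17059 passed the filter on dim signals and were tested, and 9445 of these had exactly 1 named gene. The labels say that the samples of a group were lysed separately and do not say whether the plants were grown separately, so p-values concern the spread between these samples. SEs and p-values of single probe sets rest on moderated variances. These combine a probe set's own spread (4 residual degrees of freedom) with that of probe sets of like signal (10.4 prior degrees of freedom). They can therefore understate the spread of a single variable gene. Signals correlated at r = 0.976 to 0.98 across probe sets between arrays of one group and at 0.9689 to 0.9756 between arrays of different groups. The number of arrays limits the precision of every value given here.

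The comparison asked which transcripts differ between seedlings with and without the mutation. AT4G12490 and its neighbour AT4G12500, which encode proteins of the lipid-transfer and protease inhibitor family, rose by a log2 change of 2.52 ± 0.20 (SE) and 2.28 ± 0.24. AT4G12490 went from a signal of 128 ± 34.1 (SD, n = 3) in the wild type to 813 ± 203 (n = 3) in the mutant. In the other direction, *ARPN*, which encodes a plantacyanin, fell by 1.74 ± 0.17, from a signal of 677 ± 133 to 191 ± 32.4. The thionin gene *THI2.1* and the defensin gene *PDF2.1* were lower in the mutant too, but the defensin gene *PDF1.4* rose by 1.27 ± 0.18.

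Among the other 8 of the 10 named genes with the largest rises, the chitinase family gene AT2G43620 rose by 1.54 ± 0.14, from 842 ± 166 to 2470 ± 335 (adjusted p = 4.47e-05). The peroxidase gene AT5G64120 rose by 1.53 ± 0.15, from 785 ± 141 to 2310 ± 447 (adjusted p = 6.27e-05). AT3G16670, a gene of the pollen Ole e 1 family, rose by 1.5 ± 0.11, from 407 ± 32.1 to 1180 ± 55.4 (adjusted p = 4.49e-06). AT4G22470, a further member of the lipid-transfer and protease inhibitor family, rose by 1.43 ± 0.19, and AT1G22570, of the NPF family of transporters, by 1.35 ± 0.21. *GAT1_2.1*, which encodes a class I glutamine amidotransferase, rose by 1.79 ± 0.28, AT1G29090, a papain-like cysteine peptidase gene, by 1.74 ± 0.38, and AT1G02470 by 1.54 ± 0.33. Wild type signals of these last 3 genes were low, at means of 36.0, 26.9 and 22.4. The 25th percentile of an array lay between 39.2 and 49.7, and at such signals the log2 change understates the fold.

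Among the 10 named genes with the largest falls, *M17*, of the late embryogenesis abundant type, had the largest change, −2.02 ± 0.43 (adjusted p = 0.0372). Its wild type signal was 612 ± 550, and without wild type replicate 2 the change was −1.33 with an adjusted p of 0.0522. *ARPN* followed (adjusted p = 6.27e-05), and then AT5G53770 at −1.62 ± 0.31. *MPC*, which is related to the C-terminal domain of poly(A)-binding proteins, fell by 1.58 ± 0.24, from a signal of 268 ± 40.3 to 82.3 ± 31.1. *PDF2.1* fell by 1.57 ± 0.25, and the thionin genes AT1G66100 and *THI2.1* by 1.18 ± 0.20 and 1.09 ± 0.23. The glutathione S-transferase gene *GSTU25* fell by 1.21 ± 0.16, from 510 ± 95.1 to 210 ± 25.4 (adjusted p = 0.00123). AT1G21770 and AT5G22460 fell by 1.12 ± 0.12 and 1.06 ± 0.23. Of the 20 named genes, 13 passed in each of the 6 fits that left out 1 array. The other 7 lost the call in at least 1 of these fits: AT1G02470, AT1G29090, AT1G66100, AT5G22460, AT5G53770, *M17* and *THI2.1*. *THI2.1* had its highest adjusted p there, 0.2, and AT5G22460 passed in none of the 6.

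**Figure D1:**
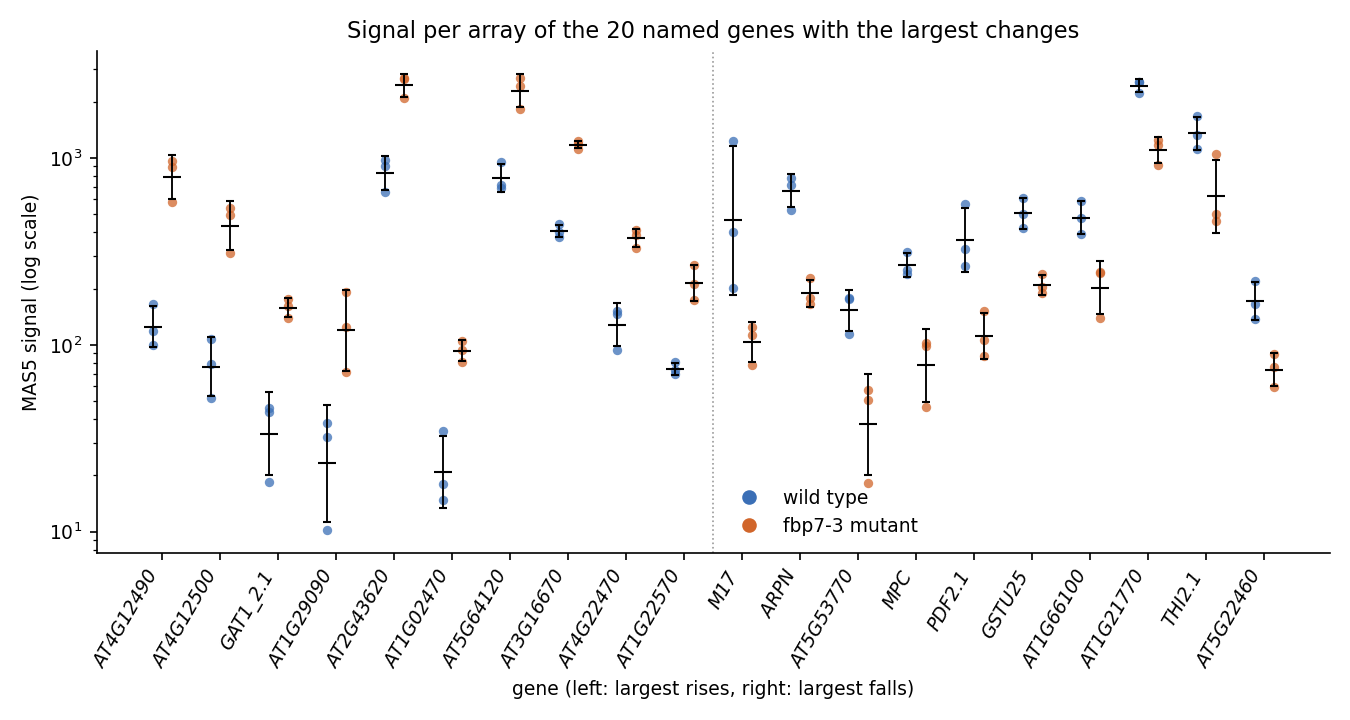
MAS5 signal on a log axis of the 20 named genes with the largest changes, 10 rises on the left and 10 falls on the right, with 1 point per array, 3 wild type and 3 *fbp7-3* mutant arrays, and a dash and bar for the mean and SD on the log scale. Non-overlapping groups were a condition for naming these genes. AT4G12490 goes from a mean of 128 to 813 while *ARPN* goes from 677 to 191.

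In all, 180 of 17059 probe sets changed, 89 higher and 91 lower in the mutant (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 80 had 1 named gene, 41 higher and 39 lower, 5 had several genes, and 95 had no gene listed in the annotation table used. At least a 2-fold change was reached by 54, 32 of them higher. At an unadjusted p under 0.05 there were 2009. All 180 had non-overlapping groups, as did 2901, or 17.01%, of the probe sets tested, where chance gives 10%. The count fell to 6 without the intensity trend in the variance model and to 75 without the filter on dim probe sets. It was 24 with an index of RNA quality in the model, and 81, 115, 89 and 74 without wild type replicate 1, wild type replicate 2, mutant replicate 2 and mutant replicate 3.

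Of 6 control ratios of RNA quality, 3 separated the groups. The 3′ to 5′ signal ratio of the GAPDH control probe sets was 1.14 ± 0.11 in the wild type and 1.36 ± 0.12 in the mutant in one series of controls. In the other series it was 2.5 ± 0.07 and 3.13 ± 0.31, where the ubiquitin ratio was 3.40 ± 0.12 and 3.79 ± 0.29. In all 3 cases each mutant array lay above each wild type array, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. The groups overlapped in the other 3, both actin ratios (0.78 ± 0.09 and 1 ± 0.23; 4.59 ± 0.32 and 5.11 ± 0.97) and the second ubiquitin ratio (1.55 ± 0.11 and 1.63 ± 0.17), with exact permutation p values of 0.3, 0.5 and 0.7.

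Of 4 probe sets with no listed gene, chosen after their values were seen, 3 changed by more than any of the 20 named genes. Probe set 252325_at rose by 3.33 ± 0.09, from a signal of 3020 ± 51.0 to 30600 ± 2470, and 254818_at by 2.96 ± 0.21, from 796 ± 353 to 5960 ± 505. Probe set 262500_at fell by 3.52 ± 0.17, from 947 ± 19.4 to 69.4 ± 18.9, and 260088_at fell by 1.91 ± 0.37. The call of 260088_at passed in 2 of the 6 fits without 1 array, with a highest adjusted p of 0.133 there, and was lost with robust eBayes (adjusted p = 0.233). The other 3 were among the 6 calls that held without the intensity trend.

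No probe set was paired with *FBP7* in the annotation table used, so the planned test of the mutated gene was not run. Probe set 262500_at, with no listed gene, had the largest fall of all tested probe sets (−3.52). Its number lies among those of the probe sets of the loci beside *FBP7*. It may measure *FBP7*, but this was not tested, so its fall is not used as a check of the labels. Of the 5 measured loci on each side of *FBP7*, in the gene order of the TAIR10.1 assembly, 9 were tested and 2 changed. AT1G21770, whose gene model overlaps that of *FBP7*, fell from 2430 ± 191 to 1110 ± 172 (adjusted p = 0.000141). It did not pass without the intensity trend (0.0659) or with the RNA quality covariate, where its change was −0.81 (0.0854). Signal from overlapping transcripts was not separated, so its change is uncertain as a change of that gene. AT1G21670 rose by 0.58 ± 0.10, from 1340 ± 152 to 2010 ± 18.6 (adjusted p = 0.0121). Without mutant replicate 2 or without mutant replicate 3, AT1G21670 did not pass, with a highest adjusted p of 0.0637, nor did it without the intensity trend (0.213) or with the RNA quality covariate (0.334).

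Groups of genes fixed before the data were examined were thinly covered: 68 of 524 listed loci were tested, and 8 of 25 lists had at least 5 tested genes. Plastid-encoded genes, which code for parts of the photosynthetic and gene expression machinery of the chloroplast, lay higher in the mutant on average, although the groups overlapped array by array. Of 69 tested, 61 had a log2 change above 0, with a median of 0.16 (camera adjusted p = 1.79e-09; adjusted p = 0.512 with an estimated correlation, which was 0.56). Only *psbN* rose over all probe sets, by 0.85 ± 0.18, from 563 ± 165 to 1010 ± 181 (adjusted p = 0.0391). It passed in 2 of the 6 fits without 1 array. Adjusted over the list alone, 7 rose, among them *ndhF* (1.01 ± 0.24) and *ndhG* (0.54 ± 0.13). Here and below, adjustment over a list alone does not correct for the number of lists, so calls that rest on it are weaker. Without wild type replicate 1 the adjusted p of the list was 0.173. The list's median log2 value, each gene centred on its mean over the arrays, was −0.39 on that array. In wild type replicate 2 it was 0.11, above −0.01 and 0.06 in mutant replicates 2 and 3. The 5S ribosomal RNA control was higher in the mutant too, at 1050 ± 327 in the wild type and 1570 ± 107 in the mutant (exact permutation p = 0.1). As in the 3 control ratios above, each mutant array lay above each wild type array. With the RNA quality index, which includes those ratios, as a covariate, the plastid-encoded list still passed at the preset correlation (camera adjusted p = 4.43e-19). A correlation of those ratios with the plastid-encoded genes over the arrays was not computed. Mitochondrion-encoded genes had a median of 0.15 over 18 probe sets and did not pass (12 genes, camera adjusted p = 0.148), except without mutant replicate 2 (0.0245).

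None of the 10 nuclear photosynthesis genes passed. Their median was 0.15, with 8 above 0 (camera adjusted p = 0.0528), and the light-harvesting genes *LHCB4.2* and *LHCB4.1* had log2 changes of 0.32 ± 0.12 and 0.24 ± 0.10. The list passed without wild type replicate 3, mutant replicate 2 or mutant replicate 3, at adjusted p values of 0.024, 0.0245 and 0.0394. None of the 5 flavonoid and anthocyanin genes passed over all probe sets (median −0.39, camera adjusted p = 0.0552). Adjusted over the list alone 2 fell, *DFR*, which encodes dihydroflavonol reductase, at −0.96 ± 0.25 and *UGT78D2*, a flavonoid glucosyltransferase gene, at −0.39 ± 0.12. The list passed without wild type replicate 2 (adjusted p = 0.00897), as did *DFR* over all probe sets (0.0478), and without mutant replicate 3 (0.0158), with no filter (0.0333) and with the RNA quality covariate (0.00242). Of 5 cold-responsive genes none passed over all probe sets and 2 fell adjusted over the list alone, *COR15A* at −1.29 ± 0.37 and *LTI30* at −0.32 ± 0.11 (camera adjusted p = 0.151). Without mutant replicate 1 the cold list passed (0.0408), and *COR15A* fell over all probe sets, at −1.81 (adjusted p = 0.00386). The 5 heat shock genes had a median of −0.39 and none passed (camera adjusted p = 0.26, or 0.0235 with the RNA quality covariate), with AT1G52560 at −0.80 ± 0.40 and AT5G48570 at −0.63 ± 0.32. The change of AT1G52560 ran from −1.41 to −0.34 over all alternatives. Its signal was 10.2 in mutant replicate 2, against 49.4 and 55.1 in mutant replicates 1 and 3. The 7 cytosolic ribosomal protein genes had a median of 0.02 (camera adjusted p = 0.446), with AT3G09200 at 0.15 ± 0.10 and AT5G20290 at 0.14 ± 0.11. Genes of the unfolded protein response, 5 in number, had a median of −0.04 (camera adjusted p = 0.373), with *CRT1b* at −0.23 ± 0.09 and *ATERDJ3B* at −0.17 ± 0.10. With an estimated correlation no list passed, and by fry none did.

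**Figure D2:**
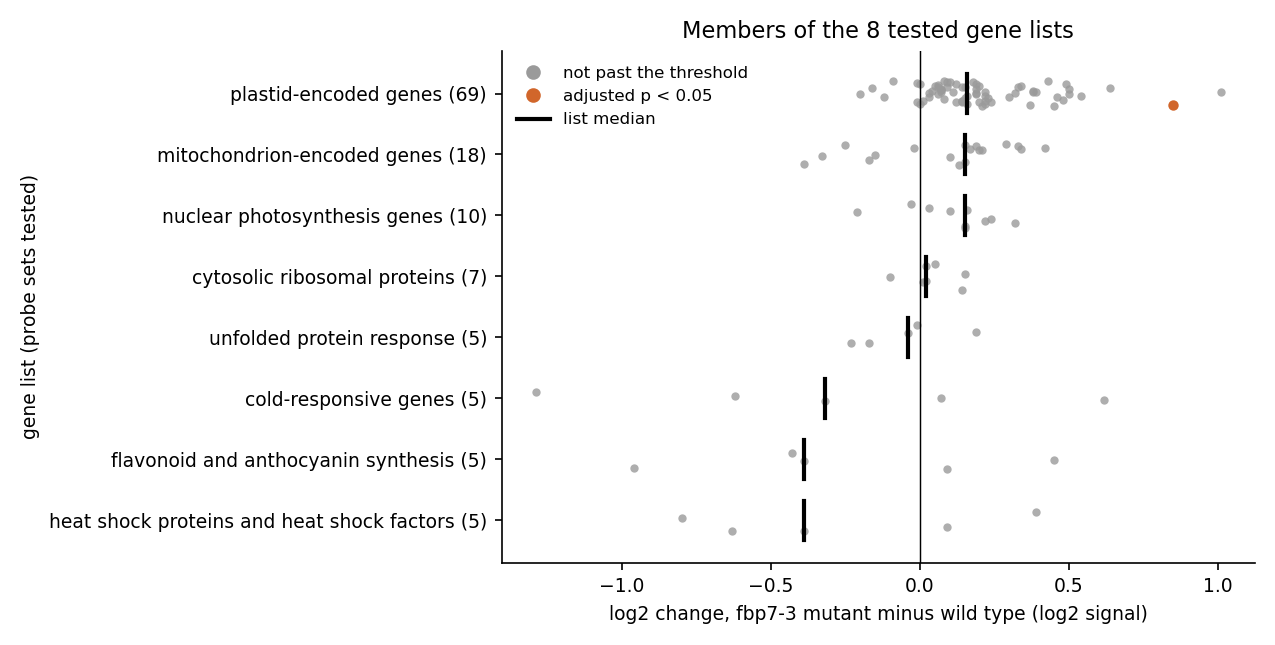
Log2 change, mutant minus wild type, of each probe set (points) in the 8 tested gene lists, with the list median as a black bar and the number of probe sets in brackets. *psbN* in the plastid-encoded list is the single member past an adjusted p of 0.05, and 61 of the 69 plastid-encoded genes lie above 0.

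The remaining lists had fewer than 5 tested genes and no list test. The circadian clock gene *GI* rose by 0.59 ± 0.12, from 531 ± 61.0 to 806 ± 80.5 (adjusted p = 0.0372), and passed in 1 of the 6 fits without 1 array. Of 2 jasmonate and ethylene defence genes *THI2.1* fell, while *PDF1.2* had a change of 0.59 ± 0.31 (adjusted p = 0.482). Of 2 oxidative stress genes *GSTU25* fell and *NDB2* was at −0.07 ± 0.17. No member passed over all probe sets in the lists that follow. Translation factors held *EIF4A-2* (0.16 ± 0.09) and AT2G40290 (−0.03 ± 0.09). The 3 genes of SCF complexes, ubiquitin and proteasome included *CUL4* (0.12 ± 0.09) and *SLY1* (−0.18 ± 0.14). The salicylic acid and immune list held *WRKY53* (−0.03 ± 0.21) and *GRX480* (−0.03 ± 0.38). Auxin genes, 4 in number, included *HAT2* (−0.30 ± 0.14) and *GH3.3* (−0.27 ± 0.19). Of 3 cell cycle genes *PRL* was at 0.39 ± 0.11, and rose adjusted over the list alone, and *AUR1* at −0.03 ± 0.12. Of 4 cell wall genes *COB* was at 0.11 ± 0.09 and *XTH18* at −0.14 ± 0.22. Of 3 glucosinolate genes AT2G31790 was at −0.23 ± 0.10 and *BCAT4* at −0.15 ± 0.13. Lists for ribosome biogenesis, abscisic acid and drought, phosphate starvation, iron homeostasis and nitrate had no tested gene.

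Markers of tissue make-up did not pass over all probe sets. The 4 root and root hair markers lay below 0, with a median of −0.42. Adjusted over the list alone, the peroxidase gene AT3G49960 fell, at −0.75 ± 0.25, and *EXPA18*, a root hair expansin gene, was at −0.30 ± 0.18. The single tested gene of the seed storage and embryo list, the isocitrate lyase gene *ICL*, was at −1.05 ± 0.42 (limma adjusted p = 0.325 over all probe sets). Adjustment over its list alone has no effect with a single gene, so no fall is called from it. The groups overlapped, with a signal of 88.5 in wild type replicate 3 and 161.2 in mutant replicate 2. Its change ran from −1.58 to −0.58 over all alternatives, and was −0.58 without wild type replicate 2.

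**Figure D3:**
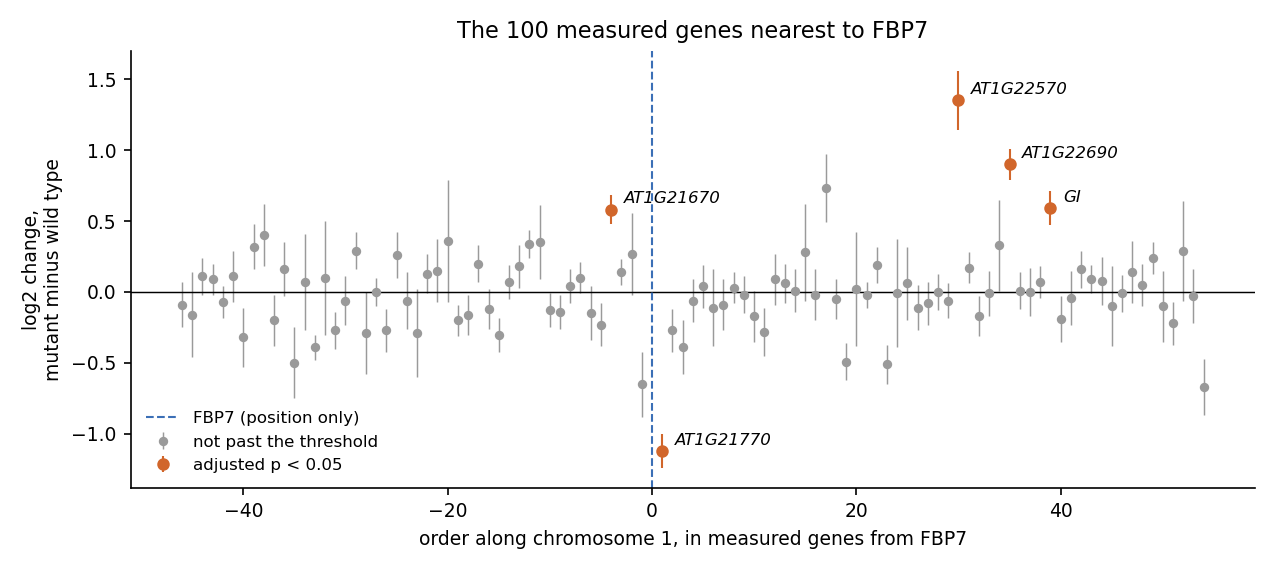
Log2 change, mutant minus wild type, with SE bars, of the 100 tested genes nearest to *FBP7* on chromosome 1, in the gene order of TAIR10.1, with the position of *FBP7* as a dashed line. AT1G21770 fell by 1.12 directly beside *FBP7*, and AT1G21670, AT1G22570, AT1G22690 and *GI* rose.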

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

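The control probe sets lie outside the gene comparison, and 7 of their signals or ratios were flagged because each mutant array lay above each wild type array. The tests against other splits of the arrays, the test with the 5S ribosomal RNA, the RNA quality covariate, and the jackknife and the repeat on probe sets chosen by size for the 3′ bias test were chosen after the results were seen.

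The 5S ribosomal RNA control had a mean signal of 1570 ± 107 (SD, n = 3) in the mutant and 1050 ± 327 in the wild type. Of the ubiquitin controls, the first series had 19100 ± 550 against 16200 ± 1290 at the 3′ end and 6260 ± 123 against 4690 ± 558 in the middle, and the second series 16300 ± 822 against 14700 ± 626 at the 3′ end. The 3′ to 5′ ratio of GAPDH was 1.36 in the mutant in the second series and 3.13 in the first, against 1.14 and 2.5, and that of ubiquitin was 3.79 in the first series, against 3.40. Each had an exact permutation p of 0.1, the smallest possible here. They were 4 of 19 Arabidopsis control probe sets and 3 of 6 ratios, where chance puts 5% of independent values in this order.

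The first pattern is the number of changed probe sets, 180: within the groups, the slope on the RNA quality index explained a median share of 0.1 of their change (95% interval −0.22 to 0.43 over the arrays, by jackknife), and 0.15 (−0.09 to 0.39) of that of the 180 with the largest changes, chosen without regard to their spread. Both shares were small, but error in the index lowers such a share, as does the choice of probe sets by their difference between the groups. The index also separated the groups, at 0.878 to 0.998 in the wild type and 1.069 to 1.334 in the mutant. A linear trend on the index as the source of most of the change is therefore not excluded, and single genes stay open. With the index as a covariate 24 probe sets passed, as the median SE of the 180 went from 0.13 to 0.20 and their median change from 0.76 to 0.71, but *M17* went from −2.02 to −0.99, AT5G53770 from −1.62 to −0.82 and 260088_at from −1.91 to −0.86. Only 1 of the 10 splits of the 6 arrays gave as many, the real one, and the highest other count was 0 (limma; up to 960 at an unadjusted p under 0.05, against 2009); 10 splits are too few for a share under 0.05, and the mutation and a difference in sample handling that follows the groups stay open.

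The second pattern is the higher level of plastid-encoded transcripts in the mutant, of which 1 array carries much: without wild type replicate 1, whose median for the list was −0.39 against −0.03 or more in the other 5, the adjusted p was 0.173. As many lists passed in 9 of the 10 splits, the real one included, with up to 4 in the others, and 4 of the 9 other splits gave a median difference for these genes as large as the real 0.155. In 9 of the 10 splits, the real one included, the list's own camera p was under 0.05. That p therefore does not set the real split apart. A candidate explanation is unequal carry-over of RNA without a poly(A) tail: the list's median followed the 5S ribosomal RNA signal over 6 arrays (Pearson r = 0.91, exact permutation p = 0.0306, adjusted over 2 relations 0.0611; Spearman rho = 0.71, exact permutation p = 0.136). Within the groups r was 0.91, but the relation rests on wild type replicates 1 and 3, with r = 0.18 over the 4 arrays left, which span a narrower range of 5S signal, and it leaves that explanation and an effect of the mutation open. For the mitochondrion-encoded list r was 0.74 (exact permutation p = 0.0764; 0.83 within groups and 0.49 without those 2 arrays) and rho 0.77 (exact permutation p = 0.103).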

How the results depend on the processing

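An RNA quality covariate and adjustment over named probe sets only were chosen after seeing the data; the cause of a change was not tested unless given. The count of 180 went to 75 with no filter and 6 without the trend (prior degrees of freedom 3.3 against 10.4), to 54 at 2-fold or more, 316 at an adjusted p under 0.1, 24 with the covariate and 57 over named probe sets only. It ran from 74 to 248 with 1 array left out. The share of higher calls, 49.4%, was 83.3% without the trend, 66.7% with the covariate, and 60.5%, 60% and 36.9% without wild type replicates 1, 2 and 3. Other settings gave 152 to 205. Same-numbered arrays did not deviate together (r = −0.005, −0.025 and −0.032), and the replicate block gave 211 calls, 164 shared, with *COR15A* among them (adjusted p = 0.00318), and 3 lists (plastid-encoded, and cold and flavonoid at 0.0338 each). The list count of 1 was 2 with no filter (flavonoid added) and with the lowest 50% left out (nuclear photosynthesis added, 0.0381), 3 with the covariate (heat shock and flavonoid added), 0 with an estimated correlation and with fry, and 0 to 3 with 1 array left out. The plastid-encoded list had adjusted p 0.512 with an estimated correlation, 0.408 with fry, 4.43e-19 with the covariate, and 2.44e-19 to 0.173 with 1 array left out. The ribosomal list turned lower with quantile normalization (adjusted p = 0.648) and without mutant replicate 1 (0.802; 0.211 to 0.943 with 1 array left out). Of 332 combinations of the 20 top genes with an alternative, 258 passed, 74 did not and 0 reversed; AT4G12490 and AT3G16670 passed in all. Median centring let *ndhG* pass (0.0472). Of the 20, 18 lost the call without the trend, 14 with the covariate, 7 with no filter, 3 with quantile normalization, 2 with robust eBayes (*M17*, adjusted p = 0.322, and *THI2.1*, 0.254), and 1 each with pseudocount 1 and the replicate block. Outside the 20, *psbN*, *GI* and 260088_at lost it with no filter, without the trend and with the covariate, AT1G21670 with the last 2 of these, *psbN* and 260088_at with robust eBayes, and *psbN* with array weights (0.0565). Only uncalled genes near 0 changed sign: *GRX480* (0 with pseudocount 1, 0.34 with the covariate, −0.35 to 0.19 with 1 array left out), *NDB2* (0.12; −0.20 to 0.11), *AUR1* (0.05; −0.10 to 0.03), AT2G40290 (0), *BCAT4* (0.03), *XTH18* (−0.34 to 0.02) and *WRKY53* (−0.11 to 0.06). The *FBP7* alternatives were not run. Signals near or below an array's 25th percentile limit the folds of dim genes.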

Other observations

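The groups of protein families and the counts around *FBP7* were chosen after the calls were seen; the test of uncalled genes in the region was not. Of 10 tested genes for proline-rich and lipid transfer-like proteins with 8 conserved cysteines, 4 rose and 0 fell. Beside AT4G12490, AT4G12500 and AT4G22470 these included AT1G62510, at 0.65 ± 0.15 (adjusted p = 0.0489). The other 6 had a median of 0.29, with 4 above 0 (camera adjusted p over both groups = 0.156; adjusted p = 0.46 with an estimated correlation), so a shift of the family beyond the called genes was not shown. AT2G45180 had a high signal, 15900 ± 1550 in the wild type and 20500 ± 1330 in the mutant, with an adjusted p of 0.106.

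Thionin and defensin genes did not move one way. Of 9 tested, 3 fell (*PDF2.1*, AT1G66100 and *THI2.1*) and 1 rose, the defensin gene *PDF1.4*, by 1.27 ± 0.18, from a signal of 158 ± 41.2 to 399 ± 41.5 (adjusted p = 0.00266). *THI2.2* was at 0.58 ± 0.19 and *LCR68* at −0.37 ± 0.09 (adjusted p = 0.215 and 0.0648). The camera adjusted p was 0.0756 for the whole group and 0.786 without the called genes.

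The third pattern is a group of changed genes near *FBP7*: of the 100 tested genes nearest to it, 5 changed, 4 higher and 1 lower: AT1G21770, AT1G21670, AT1G22570, *GI* and AT1G22690, which rose by 0.90 ± 0.11. Random placement of the changed genes gives 0.85 on average and as many with a probability of 0.0016 (0.0032 adjusted over 4 region sizes), and 0.66% of all windows of 100 genes held as many. Without AT1G21770 the probability was 0.00962 for 100 genes and 0.00653 for 200, but 0.34 for 50 and 0.184 for 25, so chance placement stays open; with 1 array left out 3 to 6 genes of the 100 changed (probability 0.000464 to 0.00575), in fits that share most arrays and keep AT1G21770 and so are no separate test. A candidate explanation is a linked chromosome segment that differs between the lines: of the 95 uncalled genes there 10.5% had an unadjusted p under 0.05, close to the median of 10.1% over all windows of 100 genes and below their 95th percentile of 15.3%, which leaves it open. An effect of the mutation on nearby genes stays open too; sequence differences under the probes were not examined.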
